A study of Mus musculus with 2 samples.

How the data were processed

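Total RNA of cultured ureters was measured on 2 two-colour Agilent arrays, each with mutant and control RNA in opposite dyes. Per the labels, 150 ng of RNA went into each labelling, the strain was NMRI, and the dyes were swapped between the arrays. The labels say neither how many embryos went into an RNA sample nor whether the replicates came from separate litters. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Both arrays lay on the same slide and shared 1 scan, so no batch of that kind could be tested.

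The deposited scanner files hold intensity values, the mean pixel signal of each spot and the median signal around it, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. The processed intensity values were background-subtracted with spatial detrending and dye-normalised by a linear and LOWESS step, per the file headers. The log10 ratios, red over green of those processed signals, were made by the same software, per the file headers. The authors' value table holds a score per probe, a signed fold change whose way of averaging spots is not given in the sources used here. Its scale and direction were worked out by setting each column against the scanner values. No value lay between -1 and 1, the median was 1 on both arrays, and 8097 and 9100 probes stood at exactly 1. On the log2 scale it correlated with red over green at r = 0.84 on array 1 and at r = -0.85 on array 2, across probes, so the direction is mutant over control on both. Sizes lay within 0.1 log2 of the software's ratio for 80.9% and 81.0% of 39429 probes. Why values were set to 1, and whether they were centred, stays unknown. Probe coordinates are those of mm9, per the file headers.

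The main values came from the mean and background signals with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, which pulls the ratios of dim probes towards 0. Ratios were normalised by loess within each array, with control spots at weight 0 and outlier spots left out, 3.17% of gene spots on array 1 and 3.65% on array 2. No gene spot was saturated. The 19304 spots of a filler probe, 6 spots of a probe whose role is not given in the sources used here, and other control spots were left out of the tests. Each probe lay in 4 spots, which were averaged. Of 39429 probes, 28328 were named through an accession and 3400 through a symbol in the RefSeq table of a later assembly, used for names alone, and 7701 kept the name in the file, which can be old. A gene was represented by its brightest probe. Of 5395 symbols with more than 1 tested probe, 1924 had probes in opposite directions, 45 of them among the called genes. A probe was tested if well above background on both arrays in at least 1 genotype, which left 28915 probes and 22070 genes, 17459 of these with a symbol.

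Ratios were turned to mutant over control by the dyes in the labels and tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degree of freedom was 1 and the prior added 7.45. A dye effect of a probe cancels in the mean and stays in the spread. Where a gene was not well above background in the control RNA on either array, the mutant signal was set against the higher of the dim probe's signal and the lowest signal well above background on each array, as a lower bound on the fold. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 27 lists, beside camera with an estimated correlation and fry. There are 7 genes that stand in 2 lists each. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule names the targeted genes and Tbx18, the 12 largest rises and 12 largest falls among called genes with a symbol, and the 4 genes with the smallest p of each list that passed or that answered a main question. It also takes the sex-linked genes as a check of the labels. For other lists it allows counts and medians. Some genes that the rule names are not reported here.

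The fit was tested on 10 simulated pairs of arrays with 22070 genes and 200 of them changed. It called 32.0% of genes changed by 0.5 log2, 99.4% of those changed by 1 and 100% of those changed by 2, each with the right sign. The share of false calls had a median of 12.5% and ran from 6.13% to 29.2%, where 5% was aimed at, and the fitted prior degrees of freedom ran from 7.57 to 26.7 where 7.45 was simulated. The median SD between the spots of a probe was 0.05 log2 on each array, against 0.11 between arrays. Median signal over the filler probe was 7.20 (control) and 3.09 (mutant) on array 1, and 4.26 (control) and 5.12 (mutant) on array 2. The number of arrays limits the precision. Alternatives covered the background correction, the normalisation, the authors' value table, the filter, the probe rule, the variance model, separate channels, the threshold, the list test and each array alone.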

Results

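The series compared total RNA of ureters from mouse embryos that lacked Fgfr1 and Fgfr2 in the Tbx18-Cre lineage with RNA of control ureters. Tbx18 is a transcription factor of the mesenchyme around the ureteric epithelium, and Cre expressed from its locus removes floxed alleles in that mesenchyme and its descendants. The labels list no Cre allele for the controls, which carried floxed alleles of both receptor genes. Ureters were dissected at stage E15.5 and grown on membranes for 6 days. The comparison asks which transcripts of the cultured ureter changed when both receptors were lost from the mesenchyme. By those labels, receptor loss cannot be told apart here from the presence of Cre at the Tbx18 locus. There were 2 arrays, each with 1 mutant and 1 control RNA side by side in opposite dyes. Array 1 is labelled male and holds the mutant RNA in Cy5, and array 2 is labelled female and holds it in Cy3. Replicate, sex label and dye orientation therefore cannot be told apart. Between 70.3% and 78.3% of the gene spots were well above background in the 4 channels. The number of arrays, 2, limits the precision of every value. Ratios below are log2 of mutant over control, given as mean ± SD over the 2 arrays.

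The targeted genes came first. Fgfr1 had a log2 ratio of -0.33 ± 0.15 (SD, n = 2; limma adjusted p = 0.134), from a probe on chromosome 8 at 26685072 to 26685131 (mm9). All 3 Fgfr1 probes lay below 0 on both arrays, with means from -0.54 to -0.33. Fgfr2 was higher in the mutant RNA, at 0.56 ± 0.02 (SD, n = 2; adjusted p = 0.0309), from a probe on chromosome 7 at 137307473 to 137307532. The other Fgfr2 probe, at 137307455 to 137307514, overlaps the first, so it is not a separate check, and gave a mean of 0.76. Which exons were floxed is not given in the sources used here, so a probe outside the deleted part checks neither the genotype nor the labels. The probe of Tbx18, the gene whose locus carries the Cre, gave 0.19 ± 0.06 (SD, n = 2; adjusted p = 0.320).

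Of 22070 genes tested, 836 changed at an adjusted p below 0.05, 389 of them higher and 447 lower in the mutant RNA. All 836 went the same way on both arrays. With 2 arrays a gene of opposite signs has too large a spread to pass, so this is a property of the test. The chemokine-scavenging receptor Ackr4 rose most, by 3.05 ± 0.51 (SD, n = 2; adjusted p = 0.000365), an 8.30-fold difference, from a probe on chromosome 9 at 104000628 to 104000688 (mm9). The kidney-type cadherin Cdh16 rose by 2.43 ± 1.41 (SD, n = 2; adjusted p = 0.0194) and the early response transcription factor Egr4 by 2.06 ± 0.09 (SD, n = 2; adjusted p = 0.000365). The ephrin receptor Epha8 rose by 1.31 ± 0.28 and the mesothelial surface protein Msln by 1.08 ± 0.19. The thyroid hormone binding protein Crym rose by 1.10 ± 0.29, Fam78b by 1.06 ± 0.09 and AAdacl4fm3 by 1.03 ± 0.15. Kcnj16, an inwardly rectifying potassium channel, rose by 1.21 ± 0.91, with 1.85 on array 1 and 0.56 on array 2. Another 3 genes, the diamine oxidase Aoc1, the potassium channel Kcnj1 and the tubule protein Umod, were not well above background in the control RNA on either array. As a mean over both arrays, their mutant signal was at least 2.01-fold, 1.74-fold and 1.86-fold that of the control. This bound came from the separate channels after normalisation between arrays. Against the dim control signal, log2 ratios were 1.53 (Aoc1), 1.54 (Kcnj1) and 1.53 (Umod) on array 1. They were lower on array 2, at 0.62, 0.49 and 0.55. Adjusted p was 0.0253 for Aoc1, 0.0399 for Kcnj1 and 0.0335 for Umod.

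The largest falls were in genes of fat cells. The complement protease adipsin, Cfd, fell by 2.63 ± 1.97 (SD, n = 2; adjusted p = 0.0308), a 6.19-fold difference, from a probe on chromosome 10 at 79355302 to 79355361 (mm9). Its log2 ratio was -1.23 on array 1 and -4.02 on array 2. The melanocortin receptor partner Mrap fell by 2.39 ± 1.19 and the lipogenic regulator Thrsp fell by 2.36 ± 0.83. The adipocyte hormone Adipoq fell by 2.15 ± 1.41, the fatty acid binding protein Fabp4 fell by 1.99 ± 1.19, the lipid droplet protein Cidec fell by 1.90 ± 1.44 and the glycerol phosphate dehydrogenase Gpd1 fell by 1.89 ± 0.97. The atrial myosin heavy chain Myh6 fell by 2.17 ± 0.34 (SD, n = 2; adjusted p = 0.000827). Probes for 4 major urinary protein genes were lower too. Mup1 fell by 2.21 ± 1.59, Mup20 by 1.86 ± 1.54, Mup18 by 1.85 ± 1.22 and Mup19 by 1.84 ± 1.31. Members of this family are near-identical, so their probes can bind one another's transcripts, and the second tested Mup20 probe had a mean of 0.07.

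**Figure D1:**
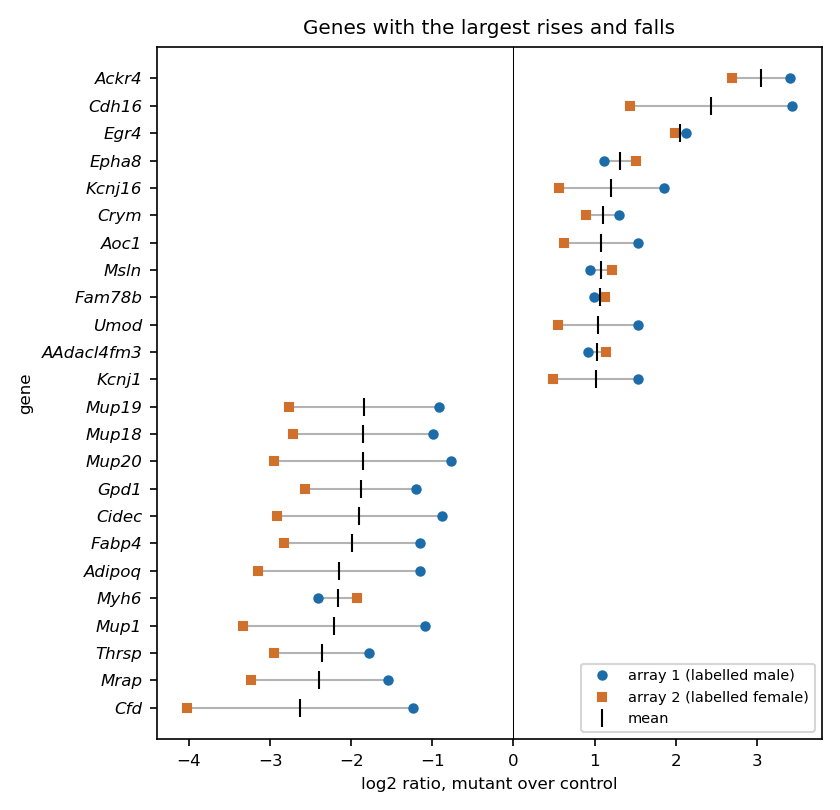
The plot shows the log2 ratio of mutant over control on each array (circles, array 1; squares, array 2) and the mean (bars) for the 12 genes that rose most and the 12 that fell most. Apart from Myh6, each gene that fell had the lower ratio on array 2, as with Cfd at -1.23 and -4.02.

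At 2-fold or more, 23 genes differed the same way on both arrays, 4 higher and 19 lower, and 1 gene went opposite ways. Across genes, which are not independent replicates, the ratios of the arrays correlated at r = 0.52. When the ratios were left as Cy5 over Cy3 on both arrays, which measures dye and array differences in place of genotype, limma called 0 genes and 77 had an unadjusted p below 0.05, against 4955 for the turned ratios. A genotype difference adds to the spread in that fit, and the setting was chosen after seeing the data.

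**Figure D2:**
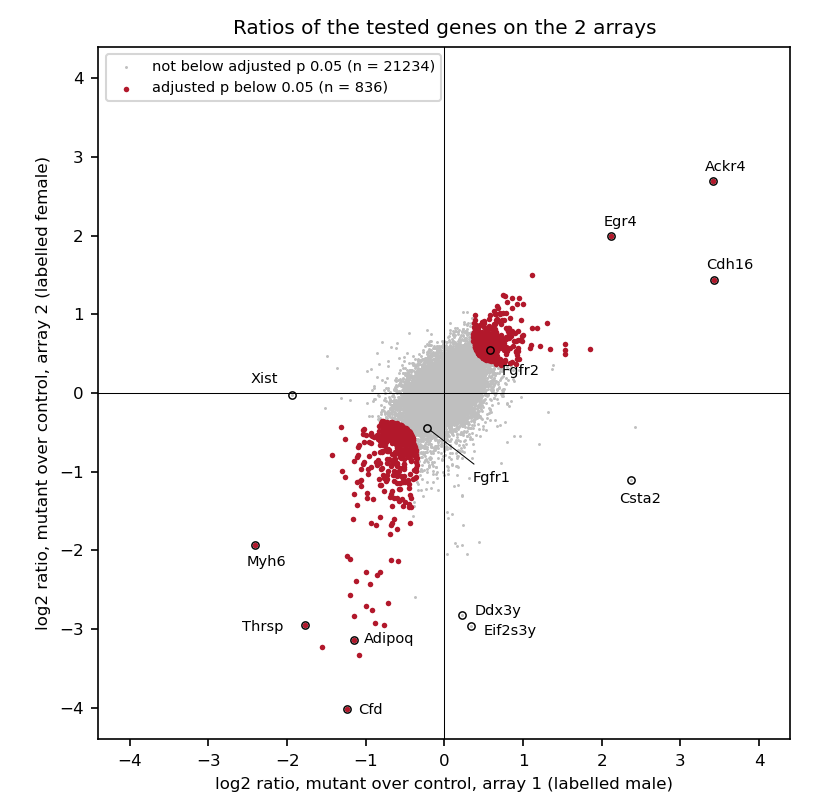
Each point is a tested gene, with its log2 ratio of mutant over control on array 1 (x axis) against array 2 (y axis). The 836 genes with an adjusted p below 0.05 are in red and lie in the quadrants of equal sign, as the test with 2 arrays requires. The Y-linked genes Ddx3y and Eif2s3y lie low on array 2 alone.

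The count depended on how the signals were processed. The processed signals of the scanner software gave 87 genes, 33.3% of them higher against 46.5% in the main setting, and the authors' value table gave 170. Median centring in place of loess gave 0 genes, with 5584 at an unadjusted p below 0.05 against 4955, and separate channels without the array as a block gave 3. With 1 residual degree of freedom the test also held its error rate loosely. In 10 simulated pairs of arrays with 200 changed genes among 22070, between 6.13% and 29.2% of the calls were false, where 5% was aimed at.

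Of 27 gene lists, 14 differed from the other genes by camera with a preset correlation, 8 higher and 6 lower. None of the 27 passed with an estimated correlation, where adjusted p lay between 0.669 and 0.782, and none passed fry, with adjusted p from 0.0701 to 0.569 for a shift one way and from 0.143 to 0.963 for changes either way. Camera with the preset correlation takes its degrees of freedom from the number of genes, so its p-values do not measure the spread between samples. With 2 arrays, camera with an estimated correlation and fry rest on 1 residual degree of freedom. The lowest unadjusted p of camera with an estimated correlation was 0.124, for neuronal and Schwann cell genes. It could hardly pass any list here, so it argues neither for nor against a shift. Each list below is given with its count of called genes over all genes tested and its count adjusted over the list alone.

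**Figure D3:**
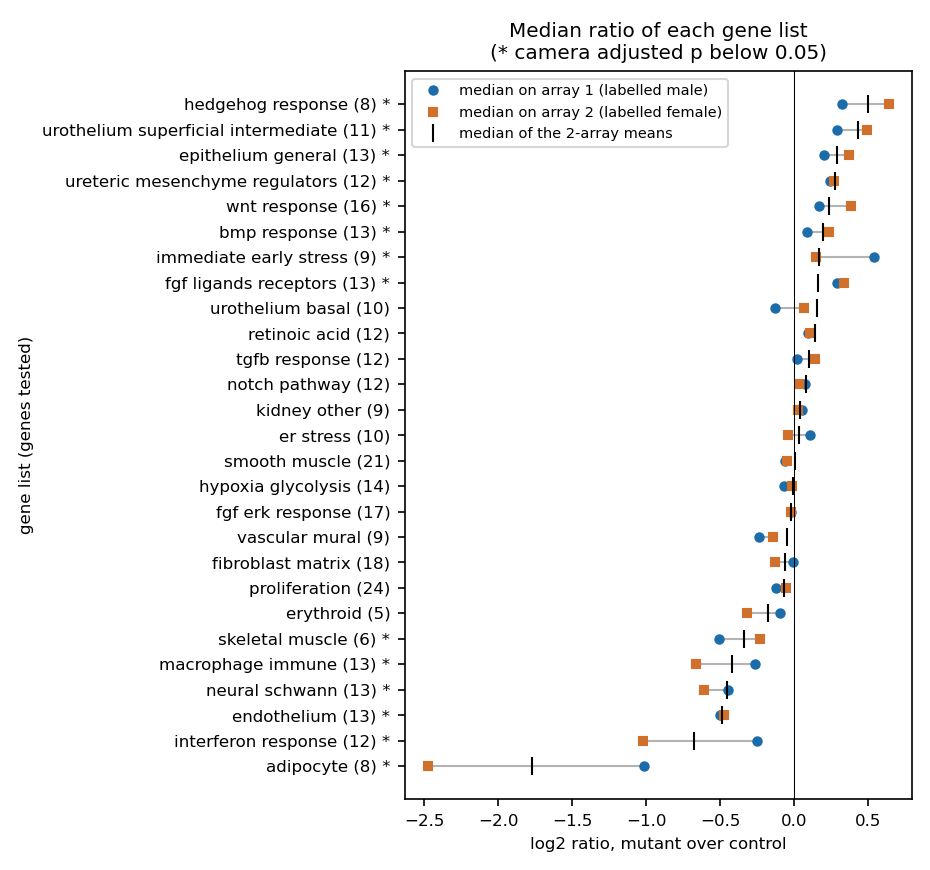
Each row is a gene list with the number of genes tested in brackets. Circles and squares give the median log2 ratio of mutant over control on arrays 1 and 2, bars the median of the means over both arrays, and an asterisk a camera adjusted p below 0.05 with the preset correlation. The adipocyte list stands lowest at -1.78 and the Hedgehog response list highest at 0.50.

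Genes of the superficial and intermediate urothelium were higher in the mutant RNA. Their list had a median log2 ratio of 0.43 (camera adjusted p = 6.46e-07; adjusted p = 0.669 with an estimated correlation), and 10 of its 11 tested genes lay above 0 on both arrays. There 4 genes rose and 7 did not pass, and 8 rose when adjusted over the list alone. The uroplakin Upk1a rose by 0.97 ± 0.15 (SD, n = 2; adjusted p = 0.0116) and the barrier transcription factor Grhl3 by 0.82 ± 0.02. The cornified envelope protein gene Sprr1a rose by 0.54 ± 0.07 and the uroplakin Upk3b by 0.55 ± 0.20. General epithelial genes had a median of 0.29 (camera adjusted p = 1.15e-06; adjusted p = 0.669 with an estimated correlation). In that list 5 of 13 rose and none fell, and 6 rose when adjusted over the list alone. They included the transcription factors Gata3, at 1.00 ± 0.33, and Foxa1, at 0.79 ± 0.20, the epithelial cadherin Cdh1, at 0.80 ± 0.14, and the keratin Krt18, at 0.61 ± 0.04 (SD, n = 2). Basal urothelial genes did not shift together. Their median was 0.15, with -0.13 on array 1 and 0.07 on array 2 (camera adjusted p = 0.554), and 0 of 10 passed over all genes, while 3 rose and 3 fell when adjusted over the list alone. The laminin chain Lamb3 had a ratio of 0.49 ± 0.13, and the basal transcription factor Trp63 had 0.45 ± 0.02 with its 4 probes in both directions. The basal keratin Krt5 had -0.46 ± 0.30.

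Targets of Hedgehog signalling rose as a group. The list had a median of 0.50, with 0.32 on array 1 and 0.64 on array 2 (camera adjusted p = 0.000617; adjusted p = 0.669 with an estimated correlation), with 4 of 8 genes higher, 0 lower and 4 not passing, and 6 higher when adjusted over the list alone. The receptor Ptch1 rose by 0.82 ± 0.20 (SD, n = 2; adjusted p = 0.0177) and the transcription factor Gli1 by 0.57 ± 0.18. The forkhead genes Foxl1 and Foxf1, which are known targets in mesenchyme, rose by 0.69 ± 0.17 and 0.66 ± 0.38. The other 4 included Bmp4, at -0.19, named after its value was seen. The WNT response list had a median of 0.23, with 0.16 on array 1 and 0.38 on array 2 (camera adjusted p = 0.000497; adjusted p = 0.669 with an estimated correlation), with 3 of 16 genes higher, 0 lower and 13 not passing, and 5 higher when adjusted over the list alone. The transcription factors Sp5 and Lef1 rose by 0.80 ± 0.03 and 0.48 ± 0.03, the feedback inhibitor Nkd1 rose by 0.76 ± 0.17, and the inhibitor Apcdd1 had a ratio of 0.49 ± 0.21 (SD, n = 2; adjusted p = 0.0590).

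BMP response genes had a median of 0.20, with 0.083 on array 1 and 0.23 on array 2 (camera adjusted p = 0.0248; adjusted p = 0.669 with an estimated correlation), a call that median centring ended at an adjusted p of 0.0770. In this list 1 of 13 genes rose, Msx2 by 0.55 ± 0.17 (SD, n = 2; adjusted p = 0.0391), and 2 rose when adjusted over the list alone. Smad9 and Smad7 had ratios of 0.53 ± 0.32 and 0.27 ± 0.08, and Hey1 had -0.23 ± 0.00. Retinoic acid genes had a median of 0.14 (camera adjusted p = 0.294). In that list 0 of 12 passed over all genes, and 4 rose and 2 fell when adjusted over the list alone. Its synthesis enzymes went both ways, Aldh1a2 at 0.42 ± 0.24 and Aldh1a3 at -0.51 ± 0.47, and the binding protein Crabp1 had -0.40 ± 0.02 and the transglutaminase Tgm2 0.39 ± 0.25.

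Genes that respond to FGF and ERK signalling showed no common shift. Their median was -0.02 and their mean 0.04 (camera adjusted p = 0.619), and 1 of 17 passed, Egr1, which rose by 0.85 ± 0.34 (SD, n = 2; adjusted p = 0.0216) and was the 1 gene that passed when adjusted over the list alone. The feedback inhibitors Spry2 and Spred2 had ratios of 0.23 ± 0.16 and 0.22 ± 0.12, and Ier3 had -0.36 ± 0.14. FGF ligands and receptors had a median of 0.16, with 0.29 on array 1 and 0.33 on array 2 (camera adjusted p = 0.0201; adjusted p = 0.669 with an estimated correlation). The call was lost on ranks (adjusted p = 0.0846) and with the mean over the probes of a gene (adjusted p = 0.0540). In that list 3 of 13 genes rose, and 6 rose and 2 fell when adjusted over the list alone. Besides Fgfr2, the receptor Fgfr3 rose by 0.71 ± 0.07 and Fgfr4 by 0.64 ± 0.10, though the second tested Fgfr4 probe had a mean of -0.07, and the ligand Fgf1 had a ratio of 0.38 ± 0.04 (SD, n = 2). The immediate early list, which shares Egr1, had a median of 0.17, with 0.54 on array 1 and 0.15 on array 2 (camera adjusted p = 0.0294; adjusted p = 0.669 with an estimated correlation). Its median was -0.0047 under median centring, where the call was lost, as it was on ranks (adjusted p = 0.0846). There 2 of 9 genes rose, Egr1 and Jun, the latter by 0.53 ± 0.07, and 3 when adjusted over the list alone, while Ier2 had 0.44 ± 0.19 and Atf3 -0.27 ± 0.18.

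Smooth muscle genes showed no common shift. The list had a median of 0.00 and a mean of -0.09 (camera adjusted p = 0.554), with 0 of 21 genes higher and 1 lower, and 1 higher and 2 lower when adjusted over the list alone. Under median centring its median was -0.30, or -0.16 relative to all genes (camera adjusted p = 0.110). Acta2, the smooth muscle actin, had a ratio of 0.00 ± 0.03 (SD, n = 2; adjusted p = 0.994) and is named after its value was seen. The gene that fell, by 1.14 ± 0.22 (SD, n = 2; adjusted p = 0.00986), was the muscle creatine kinase Ckm, which skeletal muscle also expresses. Pcp4 had -0.91 ± 0.75, the coactivator Myocd 0.45 ± 0.01 and the actin-binding protein gene Synpo2 -0.35 ± 0.18. Fibroblast and matrix genes had a median of -0.06, with -0.0084 on array 1 and -0.13 on array 2 (camera adjusted p = 0.542), with 2 of 18 lower and 0 higher, and 5 higher and 3 lower when adjusted over the list alone. The matrix proteins Dpt and Postn fell by 0.96 ± 0.22 and 0.57 ± 0.04 (SD, n = 2), while Cd34 had -0.43 ± 0.03 and the collagen chain Col1a2 0.58 ± 0.41. Regulators of the ureteric mesenchyme had a median of 0.28 (camera adjusted p = 0.00220; adjusted p = 0.669 with an estimated correlation), with 1 of 12 genes higher, and 6 higher when adjusted over the list alone. Sox9 rose by 0.73 ± 0.29 (SD, n = 2; adjusted p = 0.0247), and Tshz3, Tbx3 and Tbx2 had ratios of 0.49 ± 0.21, 0.59 ± 0.41 and 0.43 ± 0.10.

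Proliferation genes had a median of -0.07 (camera adjusted p = 0.366), and 0 of 24 passed over all genes or when adjusted over the list alone. Ccna2, Ccnb1 and Pcna had ratios of -0.27 ± 0.12, -0.26 ± 0.21 and -0.25 ± 0.16, and Plk1 had 0.27 ± 0.11. Median centring moved the median of all genes from -0.02 to -0.14, and the list was then lower at an adjusted p of 0.0158, with a median 0.14 below that of all genes.

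Genes of several other cell types were lower in the mutant RNA. The adipocyte list had a median of -1.78, with -1.02 on array 1 and -2.48 on array 2 (camera adjusted p = 8.66e-08; adjusted p = 0.669 with an estimated correlation). In it 7 of 8 genes fell, and 8 when adjusted over the list alone, with the adipocyte hormone Retn at -1.65 ± 0.59 (SD, n = 2; adjusted p = 0.00999). Endothelial genes had a median of -0.49 (camera adjusted p = 1.15e-06; adjusted p = 0.669 with an estimated correlation). There 7 of 13 fell, and 10 when adjusted over the list alone, among them the junction genes Cdh5, by 0.69 ± 0.15, and Esam, by 0.68 ± 0.09, the sialomucin Emcn, by 0.63 ± 0.02, and Sox17, by 0.61 ± 0.17 (SD, n = 2). Neuronal and Schwann cell genes had a median of -0.46 (camera adjusted p = 6.63e-06; adjusted p = 0.669 with an estimated correlation). Here 6 of 13 fell, and 8 fell and 1 rose when adjusted over the list alone. The noradrenaline enzyme Dbh fell by 0.97 ± 0.01, and the neuronal genes Stmn2 and Prph by 1.00 ± 0.34 and 0.78 ± 0.05 (SD, n = 2). Macrophage genes had a median of -0.42, with -0.26 on array 1 and -0.67 on array 2 (camera adjusted p = 5.76e-07; adjusted p = 0.669 with an estimated correlation). In this list 4 of 13 fell, and 8 when adjusted over the list alone, with the mannose receptor Mrc1 falling by 0.79 ± 0.30, Fcer1g by 0.62 ± 0.06, Cd14 by 0.56 ± 0.12 and C1qa by 0.59 ± 0.33.

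Interferon response genes had a median of -0.68, with -0.25 on array 1 and -1.02 on array 2 (camera adjusted p = 1.74e-06; adjusted p = 0.669 with an estimated correlation). Of 12 tested, 3 fell, and 7 when adjusted over the list alone, with Isg15 falling by 0.88 ± 0.00, Ifi44 by 0.81 ± 0.35 and Bst2 by 0.54 ± 0.23, while Oasl2 had -0.67 ± 0.45 (SD, n = 2). Skeletal muscle genes had a median of -0.34, with -0.51 on array 1 and -0.23 on array 2 (camera adjusted p = 0.000255; adjusted p = 0.669 with an estimated correlation). Of 6 tested, Ckm and the fast troponin Tnnc2 fell, the latter by 0.83 ± 0.10, and 3 fell when adjusted over the list alone, while Myh8 had -0.44 ± 0.21 and Acta1 -0.23 ± 0.09. The remaining 7 lists did not pass, with camera adjusted p from 0.190 to 0.554. Their medians were 0.10 for TGF-beta response genes, 0.08 for Notch pathway genes, 0.04 for genes of other kidney cells, -0.05 for vascular mural cells, -0.18 for erythroid genes, -0.01 for hypoxia and glycolysis and 0.03 for endoplasmic reticulum stress. On arrays 1 and 2 the medians were 0.015 and 0.14 for TGF-beta, 0.073 and 0.029 for Notch, 0.050 and 0.022 for kidney, and -0.24 and -0.15 for mural cells. They were -0.095 and -0.32 for erythroid genes, -0.068 and -0.019 for hypoxia, and 0.11 and -0.041 for endoplasmic reticulum stress. Of these, 1 kidney gene rose, 2 of 9 mural genes fell, and none of the other lists' 53 members passed over all genes tested. Adjusted over the list alone, the counts were 2 higher for Notch, 1 higher for kidney, 2 lower for mural cells and 0 for the others.

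The sex-linked genes followed the labels in part. On the array labelled male, log2 intensity of Xist was 8.74 in the control RNA and 6.80 in the mutant RNA, where it was not well above background, while on the array labelled female it was 11.4 in both. The Y-linked gene Ddx3y stood at 12.4 and 12.6 in control and mutant RNA on the array labelled male. On the array labelled female it stood at 9.38 in the control RNA and at 6.55, not well above background, in the mutant RNA. Eif2s3y gave 12.5 and 12.9 on the array labelled male, and 9.67 and 6.70 on the array labelled female. Uty was well above background on the array labelled male alone, and Kdm5d in no channel. With the 876 genes on X and Y left out, a choice made after seeing the data, 826 genes changed, 389 higher and 437 lower.

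**Figure D4:**
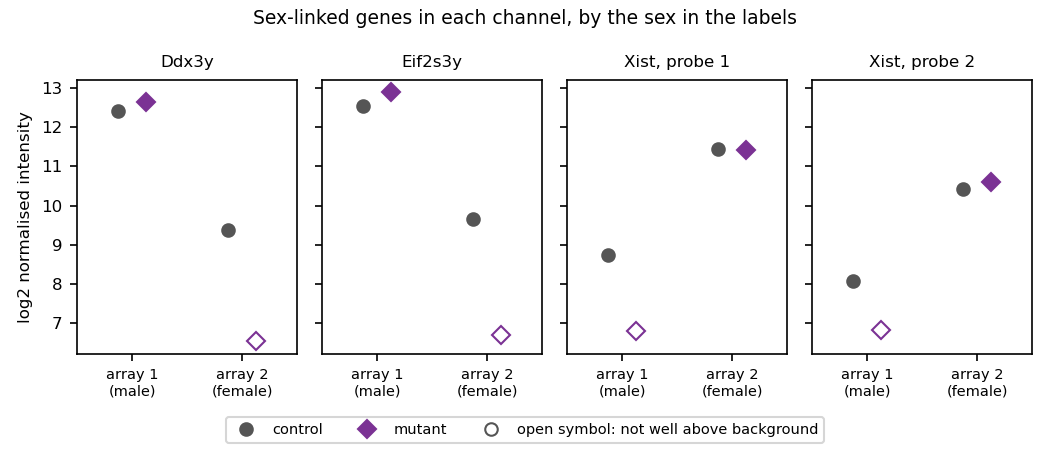
Each panel is a probe, with log2 normalised intensity (y axis) of control RNA (circles) and mutant RNA (diamonds) on the arrays labelled male and female. Open symbols were not well above background. The control RNA of the array labelled female reads 9.38 for Ddx3y, and that of the array labelled male 8.74 for Xist, while the mutant RNA reads 6.55 and 6.80 there.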

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

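The correlation over autosomal genes in this part was chosen after the result was seen. The Y-linked genes moved opposite ways on the arrays. Ddx3y had a log2 ratio of 0.23 on array 1 and -2.82 on array 2, and Eif2s3y had 0.34 and -2.97, a difference between the sex labels that was not tested as such, with 1 array for each. The tables argue against sex composition as a main source of the autosomal differences, since the sex mismatch runs opposite ways on the arrays while their ratios over 21027 autosomal genes correlated at r = 0.53, across genes that are not independent replicates. Control pools that held tissue of the other sex remain a candidate explanation, as Xist was well above background in the control RNA of the array labelled male and Ddx3y in that of the array labelled female. The test on 4 genes that escape X inactivation left this open, with a median difference of 0.16 between arrays 2 and 1 and a range from -0.56 to 0.22. No biological explanation was tested.

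A probe whose role is not given in the sources used here was bright on array 1 and near the filler probe on array 2. Its signal over that of the filler probe was 1881 in the control channel and 988 in the mutant channel of array 1, against 0.92 and 1.05 on array 2, and it entered no comparison.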

How the results depend on the processing

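The settings with unturned ratios and without X and Y genes were chosen after seeing the data. Against 836 genes, the count was 1907 at an adjusted p below 0.10, 1307 with trend and robust eBayes, 170 with the authors' value table, of which 147 were among the 836, and 87 with processed signals, of which 71 were. Limma called 0 genes under median centring (5584 at an unadjusted p below 0.05) and 0 for unturned ratios (77). Separate channels with no replicate block, and dye as covariate, gave 3 genes (1496 at an unadjusted p below 0.05). In the other 7 settings the count stayed within 1.5 times 836, from 713 to 1213. Against 23 genes at 2-fold on both arrays, processed signals gave 80, the authors' values 63 and median centring 44, and single arrays gave from 62 to 156 genes, without a test. The causes were not tested.

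With an estimated correlation the medians stayed at 0.43 for superficial urothelium, 0.50 for Hedgehog, 0.20 for BMP and 0.23 for WNT, and adjusted p became 0.669 for each. Median centring, which shifted the median of all genes to -0.14, gave 0.017 for BMP (0.16 relative to all genes, call lost), -0.29 for proliferation (call gained) and -0.0047 for the immediate early list (0.14 relative to all genes, call lost), and the cause was not tested. It gave 0.13 for superficial urothelium (0.27 relative to all genes, call kept) and -0.30 for smooth muscle (-0.16 relative to all genes, not called). FGF ligands and receptors missed the threshold with the mean over probes (adjusted p = 0.0540), and on ranks both they and the immediate early list did (adjusted p = 0.0846 each). No list call held with an estimated correlation or by fry, and the other camera calls held with the preset correlation in the other settings and on ranks. On single arrays the medians ran from -0.067 to -0.047 for smooth muscle, -0.13 to -0.0084 for fibroblast and matrix genes, -0.13 to 0.066 for basal urothelium, 0.083 to 0.23 for BMP, 0.32 to 0.64 for Hedgehog, 0.16 to 0.38 for WNT, 0.094 to 0.10 for retinoic acid and -0.12 to -0.059 for proliferation. Of 101 named genes only Tbx18 changed sign, to -0.02 under median centring. Of the 24 genes that rose or fell most, 11 passed with processed signals, 11 with the value table, 8 with trend and robust eBayes, 3 with separate channels and 0 under median centring. Low signal over background, 3.09 in the mutant channel of array 1, limits what can be said of dim genes.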

Other observations

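The tests on adipocyte, endothelial, neuronal and macrophage genes were chosen after the result was seen, except that on brown fat, and the condition on untested kidney markers was added afterwards. Genes in this part were picked after their values were seen. Among the genes that fell by about the same amount on both arrays were the gap junction gene Gja5 (-1.08 ± 0.03), the neurofilament gene Nefl (-1.12 ± 0.01), the matrix gene Aspn (-1.12 ± 0.08) and the muscle caveolin Cav3 (-1.21 ± 0.10; SD, n = 2). Each had an adjusted p of 0.00745. The coagulation factor gene F13a1 fell by 1.27 ± 0.22 and the interferon-inducible Ifi205 fell by 1.38 ± 0.32. The desaturase Scd1 fell by 1.76 ± 0.89 and haptoglobin, Hp, fell by 1.65 ± 0.64, both more on array 2. Of genes that rose, the epithelial sodium channel subunit Scnn1b stood at 0.97 ± 0.20, the transcription factor Tfcp2l1 at 0.95 ± 0.04 and the potassium channel Kcnj10 at 0.91 ± 0.43. Some genes went opposite ways on the arrays and did not pass. Csta2 had 2.38 on array 1 and -1.11 on array 2, and Cd5l had 1.21 and -0.65.

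Genes of fat cells, vessels, nerves and macrophages were all lower in the mutant RNA, and more urothelium there as the whole cause is argued against, as the smooth muscle median (95% interval from -0.21 to 0.09) lay 1.78 above that of adipocyte genes (-2.63 to -0.38). A single admixed tissue, more of it in the control RNA, could bring these genes together, and the larger adipocyte falls on array 2 then imply larger falls of the others there. The implied values hold only if that tissue had the same make-up on both arrays, which was not tested. For endothelial genes the median difference between arrays 2 and 1 was 0.21 (-0.03 to 0.29) where -0.43 was implied. This argues only against a source of the same make-up on both arrays. For macrophage genes the difference was -0.41 (-0.74 to -0.09) where -0.19 was implied, as that source needs. Neuronal genes left it open at -0.076 (-0.24 to 0.18) where -0.37 was implied, since resampling the genes of both lists gave a gap from -0.077 to 1.08. Whether brown fat was among the fat cells is a separate question that stayed open, with a median of -0.25 for its markers on the array of the higher median, and an effect of genotype on these cells was not tested.

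Cdh16, Umod, Kcnj16 and Kcnj1, genes of kidney tubules, were higher in the mutant RNA and more so on array 1, and adherent kidney tissue is a candidate explanation. The proximal tubule median on array 1 was -0.068 (95% interval -0.47 to 0.23) and the distal nephron median -0.045 (-0.12 to 0.30), both intervals below the 0.5 set beforehand as the bound against it. That bound was set aside after the values were seen, because the filter on dim probes kept 8 of 14 proximal and 9 of 20 distal genes, below the 80% then asked for. Of those left out, 2 of 6 proximal and 4 of 11 distal genes lay above 0.3 on array 1, and 2 proximal and 1 distal genes were above background there in the mutant RNA and not in the control RNA. Some tested markers were dim too, such as Kap and Hsd11b2 at mean log2 intensities of 6.85 and 6.86. The offset pulls the ratios of such probes towards 0. With so many markers untested or dim, these lists cannot decide for or against kidney tissue. It cannot be told apart from an effect of genotype on tubule genes.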
